A study of Homo sapiens with 254 samples.

How the data were processed

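Peripheral blood mononuclear cells (PBMC), the lymphocytes and monocytes of blood, were profiled from volunteers of a malaria vaccine trial on 254 Affymetrix arrays, 1 array per volunteer and sampling time. Of these, 215 were HG-U133A 2.0 arrays with 22277 probe sets each and 39 were U133 Plus 2.0 arrays with 54675 probe sets each. Total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised, per the labels' protocols. The deposited values are log2 expression values per probe set, made by the authors with RMA from the affy package, per the submitters' processing notes, which give no version. RMA subtracts background, makes the intensity distributions of the arrays alike by quantile normalization and summarises each probe set on a log2 scale, so a change shared by most genes of an array is removed from the values. The log2 unit was checked on the values, which ran from 2.65 to 14.78 on HG-U133A 2.0 arrays and from 1.39 to 14.23 on U133 Plus 2.0 arrays. Array medians lay between 5.72 and 5.88 in the first table and between 3.68 and 3.84 in the second. The tables were normalized separately, and every test was run within a table. All columns were matched to a sample by name, and 0 were left unmatched. Arrays give no read depth, so the number of arrays limits the precision.

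Probe sets were named from the platform annotation. On HG-U133A 2.0, 19064 probe sets had 1 gene symbol, 1043 had several and 2170 had none. On U133 Plus 2.0 these counts were 41091, 1801 and 11783. Only probe sets with 1 gene were tested. XIST and genes of the Y chromosome were removed from every table before any test. A gene was represented by its probe set with the highest mean over all arrays, which affects the 4304 genes with several probe sets on HG-U133A 2.0 and the 10511 on U133 Plus 2.0. Genes were tested where at least 10% of arrays lay above the median of all values, 5.77 and 3.75 in the 2 tables. That left 7350 of 11939 genes on HG-U133A 2.0 and 13381 of 19740 on U133 Plus 2.0.

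Volunteers carry a code in the labels, 46 codes among the vaccinated, and the same code at another time marks the same person. Deviations of 2 arrays of the same volunteer from their group means correlated with a mean r of 0.50 across genes, over 0.1 in 363 of 372 pairs, against -0.009 between different volunteers. One array did not match the other arrays of its volunteer in a check for mixed-up samples, and no volunteer or array is named here. The volunteer code was therefore a fixed block in the longitudinal and interaction fits. Relative log expression, the spread of an array around the median array, set 7 HG-U133A 2.0 arrays and 2 U133 Plus 2.0 arrays apart from the others. Array batch, hybridisation day and the time from blood draw to processing are not given in the sources used here.

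Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment within each of 20 comparisons and a threshold of 0.05. Longitudinal comparisons used all vaccinated arrays of HG-U133A 2.0 in 1 fit. Outcome comparisons at a given time used the Protected, Delay and NonProtected arrays of that time. Differences between outcome groups in the change from the day of the third vaccination were tested as interaction terms. The infectivity controls were set against all vaccinated volunteers at study entry and at 2 weeks after the third vaccination. Standard errors are those of the moderated fit, and p-values are 2-sided. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

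There were 20 lists of pathway genes and cell type markers, with 442 different genes. Of these genes 3 (ICAM1, CIITA and HLA-DOB) stood in 2 lists. Lists were tested with limma's camera with a preset correlation between genes of 0.01, with camera using an estimated correlation and with fry beside it. fry asks whether the members of a list move on balance one way and does not compare them with other genes. For the per-array mean of a list, differences were tested by sign-flip permutation within volunteers or by permutation of the group labels with 100000 draws, which was added after seeing the data. So were the permutation tests of the 3' minus 5' signal of ACTB and GAPDH between groups, 24 in all with 100000 draws each. Intervals of list medians are 95% bootstrap intervals over members with 2000 draws and do not cover the correlation between genes.

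The genes named are, per comparison, the 10 with the largest rise and the 10 with the largest fall among those that passed, or else the 5 with the smallest p, and the 4 members with the smallest p of each list described. Groups, comparisons, tests, lists, this rule and most alternatives were fixed before the data were examined. Which lists were described with named members was settled after their values and their alternatives had been seen. The alternatives were no filter on dim genes, quantile normalization on top of the deposited values, the median over the probe sets of a gene, no volunteer block, the volunteer as a random block, volunteers of unknown outcome left out, only the 2 groups compared, array weights, and the mean values of 6 cell type lists as covariates. Further alternatives, added after seeing the data, left out the arrays that stood apart (8 and 2 arrays, the 8 being the 7 set apart by relative log expression and the 1 that did not match its volunteer) or used the first 2 principal components of genes below the filter as covariates.

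The fits were tested on simulated data for 5 comparisons, with 67, 67 and 66 genes changed by 0.25, 0.5 and 1 log2 among independent genes with no batch. For 72 hours against the day of the third vaccination, run on 7350 genes, 95.5% of changes of 0.25 log2, 100% of 0.5 log2 and 100% of 1 log2 were recovered. For Protected against NonProtected at 2 weeks, run on 7350 genes, these shares were 25.4%, 82.1% and 98.5%. For Protected against NonProtected 5 days after challenge, run on 13381 genes, they were 34.3%, 73.1% and 100%. For the interaction from the day of the third vaccination to 2 weeks, run on 7350 genes, they were 25.4%, 76.1% and 98.5%. For the infectivity controls against 2 weeks, run on 7350 genes, they were 41.8%, 95.5% and 100%. False calls made up 3.4% to 5.5% of calls.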

Results

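The vaccinated volunteers gave PBMC at study entry, on the day of the third vaccination, 24 and 72 hours after it, 2 weeks after it and 5 days after a challenge with malaria parasites. The labels sort them by the outcome of the challenge as Protected, Delay or NonProtected, and 7 volunteers had an unknown outcome. What defines Delay, and the vaccine arm or adjuvant of each volunteer, are not given in the sources used here, so arm was no covariate in any comparison. On HG-U133A 2.0 arrays there were 36 samples at study entry (11 Protected, 11 Delay, 14 NonProtected), 44 on the day of the third vaccination (12, 11, 14 and 7 of unknown outcome), 43 at 24 hours (12, 9, 15 and 7), 43 at 72 hours (12, 10, 14 and 7) and 37 at 2 weeks (11, 11, 15). The samples of 5 days after challenge (13 Protected, 11 Delay, 15 NonProtected) were run on U133 Plus 2.0 arrays. A further 12 HG-U133A 2.0 arrays came from infectivity controls, volunteers challenged without vaccine per the labels. Such controls serve to show that the parasites given can infect, and the labels give no sampling time for these arrays. The comparisons of 24 hours, 72 hours and 2 weeks with the day of the third vaccination ask what changed after it. Those against study entry span the earlier vaccinations, and at 2 weeks the third as well. No unvaccinated volunteer was followed over these times, so the design cannot set vaccination apart from time, handling or batch. The cross-sectional comparisons ask which expression goes with protection.

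At 24 hours after the third vaccination, genes induced by interferon rose steeply above their level on the day of vaccination. SERPING1, which encodes the C1 inhibitor of the complement system, rose by 2.88 ± 0.18 log2 (SE, 42 volunteers sampled at both times) and was higher in 42 of 42. CXCL10, a chemokine that attracts activated T cells, rose by 2.76 ± 0.21, and IDO1, an enzyme of tryptophan breakdown, by 2.55 ± 0.22. GBP1, a guanylate-binding protein of host defence, rose by 2.30 ± 0.13 and was higher in 41 of 42 volunteers. FCGR1BP rose by 2.53 ± 0.13, but its probe set can cross-hybridise with the other Fc gamma receptor I genes. Of 17 tested genes of the interferon gamma response list 16 rose and 0 fell, and 16 rose when adjusted over the list alone. They include GBP2 (1.34 ± 0.07), the tryptophan-tRNA ligase WARS1 (2.04 ± 0.12) and VAMP5 (1.74 ± 0.10), and the list had a median change of 1.17 log2. Of 26 tested genes of the type I interferon response list 25 rose (25 adjusted over the list alone), with a median of 0.92. Among these were the antiviral gene IFIT3 (1.91 ± 0.14), the transcription factor IRF7 (1.01 ± 0.09), IFI35 (1.14 ± 0.08) and IFIT5 (0.92 ± 0.08). By limma's camera both lists stood above other genes (adjusted p = 4.89e-20 and 3.63e-16). With an estimated correlation the interferon gamma call held (adjusted p = 0.0317), and the type I list had adjusted p = 0.103 with an estimated correlation. Monocyte markers (median 0.54) and T cell markers (median -0.56) moved at the same time. With the mean values of 6 cell type lists as covariates 2 of the 25 type I genes that had risen still passed upward and the list median was 0.02, against 14 of the 16 interferon gamma genes and a median of 0.48.

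A list was made for the immunoproteasome, the form of the protease that cuts peptides for presentation, and its activator PA28. It also holds POMP, PSMA5 and PSMA6, which are not particular to the immunoproteasome. All 6 tested genes of this list rose at 24 hours (6 adjusted over the list alone, median 0.55). PSMB9 rose by 0.84 ± 0.05, PSMB10 by 0.76 ± 0.05, PSME1 by 0.56 ± 0.03 and the assembly factor POMP by 0.48 ± 0.04 (camera adjusted p = 1.33e-09, and adjusted p = 0.0317 with an estimated correlation). Of 25 constitutive proteasome genes 19 rose and 0 fell (19 adjusted over the list alone), with a median of 0.13, and the list had camera adjusted p = 1.4e-06 and adjusted p = 0.107 with an estimated correlation. Of 13 MHC class I presentation genes 11 rose (11 adjusted over the list alone, median 0.16), among them the peptide transporter genes TAP1 (1.11 ± 0.07) and TAP2 (0.58 ± 0.06), TAPBPL (0.36 ± 0.04) and HLA-B (0.16 ± 0.02). Of 14 MHC class II presentation genes 11 rose and 2 fell, with the same counts adjusted over the list alone and a median of 0.39. HLA-DMA rose by 0.54 ± 0.04, HLA-DMB by 0.53 ± 0.04, HLA-DPA1 by 0.43 ± 0.04 and HLA-DRB1 by 0.41 ± 0.03, and signals of HLA genes depend on a person's alleles and can cross-hybridise. The class I list had camera adjusted p = 1.39e-05 and the class II list 1.4e-06. These became adjusted p = 0.0715 and adjusted p = 0.0626 with an estimated correlation. With cell type lists as covariates the medians were 0.25 for the immunoproteasome, 0.07 for the constitutive proteasome, 0.09 for class I and 0.14 for class II, and 6 of the 6 immunoproteasome, 7 of the 11 class I and 7 of the 11 class II genes that had risen still passed upward.

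Markers of monocytes rose while markers of lymphocytes fell at 24 hours. All 20 monocyte markers rose (20 adjusted over the list alone, median 0.54), among them FPR1 (0.86 ± 0.07), SERPINA1 (0.78 ± 0.05) and the calprotectin genes S100A9 (0.59 ± 0.05) and S100A8 (0.37 ± 0.03). All 20 T cell markers fell (20 adjusted over the list alone, median -0.56), with the transcription factor BCL11B at -0.74 ± 0.05, CD247 at -0.68 ± 0.05, CD2 at -0.61 ± 0.05 and the kinase LCK at -0.59 ± 0.05. Of 19 NK and cytotoxic markers 18 fell and 1 rose (18 and 1 adjusted over the list alone, median -0.69), including the receptors KLRF1 (-1.07 ± 0.10) and KLRB1 (-0.91 ± 0.07), IL2RB (-0.70 ± 0.06) and CST7 (-0.76 ± 0.07). KLRC3 had -1.16 ± 0.10, with a probe set that can cross-hybridise with its relatives. Of 17 B cell markers 15 fell (15 adjusted over the list alone, median -0.22), among them MS4A1, which encodes CD20 (-0.56 ± 0.09), CD79B (-0.33 ± 0.05), POU2AF1 (-0.36 ± 0.06) and BLK (-0.36 ± 0.06). Camera adjusted p was 2.56e-12 for monocytes, 1.86e-12 for T cells, 1.33e-09 for NK cells and 0.00611 for B cells. In the same order these lists had adjusted p = 0.0626, 0.0626, 0.114 and 0.49 with an estimated correlation.

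All 30 ribosomal protein genes fell at 24 hours (30 adjusted over the list alone, median -0.14), with RPL35 at -0.23 ± 0.03, RPL18 at -0.19 ± 0.03, RPS25 at -0.19 ± 0.02 and RPL11 at -0.15 ± 0.02 (camera adjusted p = 7.54e-08, and adjusted p = 0.269 with an estimated correlation). With cell type lists as covariates, whose markers moved at the same time, the ribosomal median turned to 0.03 and the list did not pass. Of 16 TNF and NF-kB target genes 8 rose and 3 fell, with the same counts adjusted over the list alone and a median of 0.11. TNFAIP2 (0.82 ± 0.06), the adhesion molecule ICAM1 (0.70 ± 0.06), BCL2A1 (0.93 ± 0.08) and NFKBIE (0.46 ± 0.04) rose, and the list had camera adjusted p = 0.0139 and adjusted p = 0.269 with an estimated correlation. Dendritic cell markers went both ways, with 2 of 10 up and 6 down (2 and 6 adjusted over the list alone, median -0.14). FCER1A, a subunit of the high-affinity IgE receptor, fell by 1.10 ± 0.11, PTGDS by 0.37 ± 0.05 and CD1C by 0.29 ± 0.06, while IRF8 rose by 0.18 ± 0.03 (camera adjusted p = 0.31). The immediate early list had 4 of 18 genes up and 6 down (4 and 6 adjusted over the list alone, median -0.07, camera adjusted p = 0.321). Of 9 plasma cell markers 7 fell and 1 rose (median -0.27, camera adjusted p = 0.266), of 15 platelet markers 10 fell (median -0.18, camera adjusted p = 0.137) and of 8 cell cycle genes 3 fell (median -0.12, camera adjusted p = 0.241). Those counts were 7 and 1, 10, and 3 adjusted over the list alone. Of 10 granulocyte markers 3 rose (median 0.17, camera adjusted p = 0.281), of 12 erythroid markers 1 rose while the median was -0.13 (camera adjusted p = 0.902), and of 34 oxidative phosphorylation genes 17 rose and 8 fell (median 0.05, camera adjusted p = 0.0848). Adjusted over the list alone they were 3, 1, and 17 and 8.

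**Figure D1:**
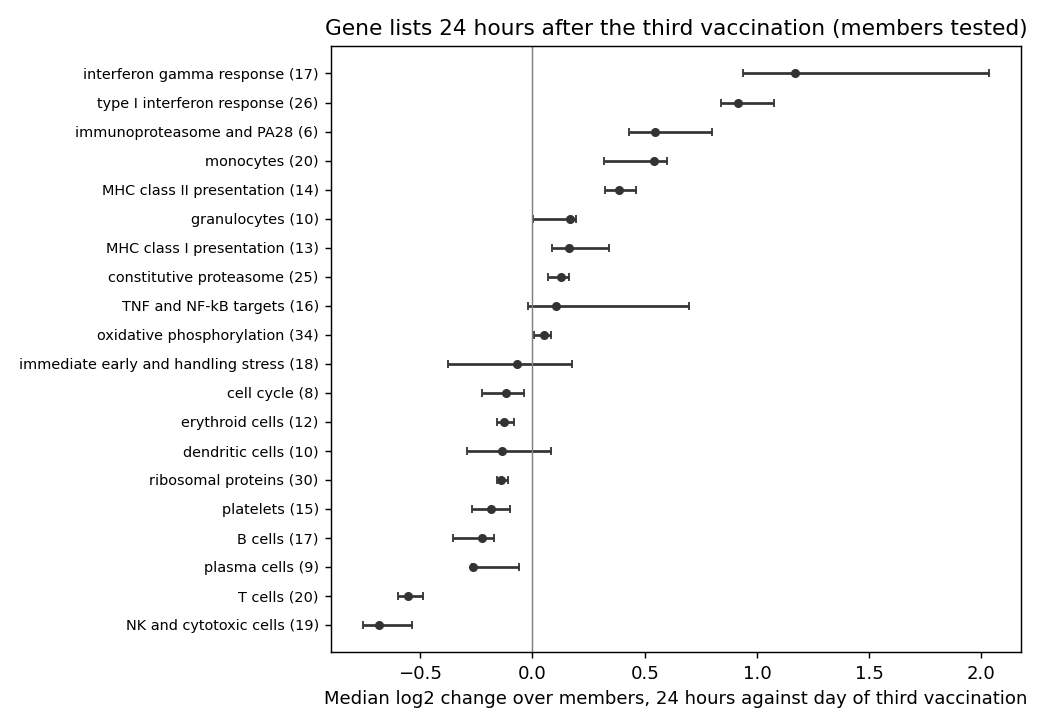
Median log2 change over the tested members of each list, 24 hours against the day of the third vaccination (x axis), for the 20 lists (y axis, number of members tested in brackets); bars are 95% bootstrap intervals over members. The interferon gamma list has the highest median (1.17) and the NK and cytotoxic list the lowest (-0.69).

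In all, 1942 genes rose and 2528 fell at 24 hours by limma with the volunteer as a block, 4470 of 7350 tested. Further large rises were those of the receptor SLAMF8 (1.99 ± 0.12), the aminopeptidase LAP3 (1.85 ± 0.11) and MYOF (1.84 ± 0.12), and further large falls those of the stress-responsive DDIT4 (-1.17 ± 0.11), the phosphatase DUSP2 (-1.12 ± 0.12), NELL2 (-0.98 ± 0.08), CD160 (-0.94 ± 0.09), HOPX (-0.93 ± 0.08) and CLIC3 (-0.92 ± 0.09). With the mean values of 6 cell type lists as covariates 1035 genes passed, 679 higher and 356 lower, of which 776 were among the 4470, so the larger share turned from lower to higher. In that fit IRF8, CD1C and RPL35 changed sign, and IDO1, IRF7, IFIT5, TAP2, BCL2A1, KLRC3, DUSP2, FCER1A, HOPX, PTGDS, RPL11, RPS25 and RPL18 did not pass. The 3' minus 5' signal, a sign of RNA quality, was higher at 24 hours by 0.125 log2 for GAPDH (95% interval 0.029 to 0.234) and by 0.064 for ACTB (-0.044 to 0.189).

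**Figure D2:**
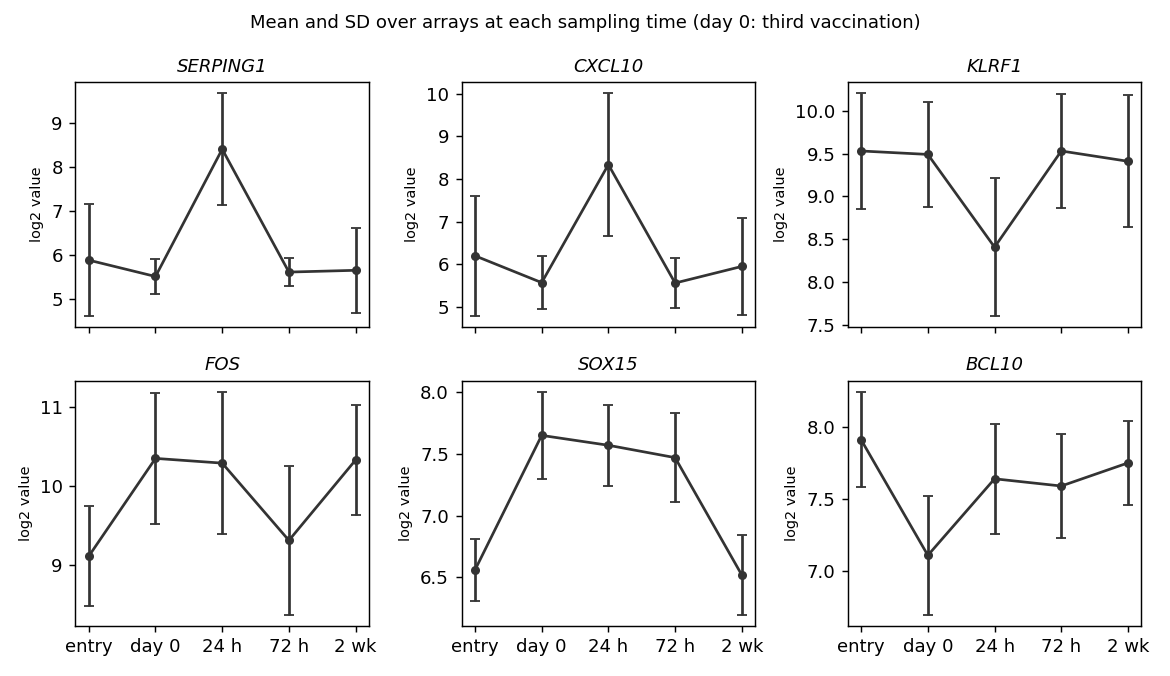
Mean log2 value (y axis of each panel, panels differ in scale) of 6 genes at study entry, on the day of the third vaccination (day 0), 24 hours, 72 hours and 2 weeks after it (x axis); points are means over 36 to 44 arrays and bars are SDs. SERPING1 and CXCL10 peak and KLRF1 dips at 24 hours, FOS is low at study entry (9.11) and at 72 hours (9.31), and SOX15 is high on the day of vaccination and at 24 and 72 hours.

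At 72 hours the immediate early genes, which respond within minutes to cell activation and handling, were lower than on the day of vaccination. Of 18 tested 14 fell and 0 rose (14 fell and 1 rose adjusted over the list alone), with a median of -0.58 log2. FOS fell by 1.05 ± 0.13 (43 volunteers sampled at both times, lower in 40 of 43), the activation marker CD69 by 0.71 ± 0.10, JUNB by 0.62 ± 0.09 and DUSP1 by 0.68 ± 0.10. This call held with an estimated correlation (camera adjusted p = 1.3e-23, and adjusted p = 0.00165 with an estimated correlation). CXCL8, the neutrophil chemokine, fell by 0.99 ± 0.20, NR4A2 by 0.97 ± 0.14, EGR1 by 0.90 ± 0.18, RGS1 by 0.84 ± 0.14 and G0S2 by 0.98 ± 0.18. Of 17 B cell markers 11 fell (15 adjusted over the list alone, median -0.23), among them BANK1 (-0.31 ± 0.07), CD79A (-0.29 ± 0.06), POU2AF1 (-0.27 ± 0.06) and HLA-DOB (-0.26 ± 0.06, a signal that can depend on alleles). The B cell list had camera adjusted p = 2.1e-13, and adjusted p = 0.0686 with an estimated correlation. Of 8 cell cycle genes 4 rose (5 adjusted over the list alone, median 0.16). These were TYMS (0.43 ± 0.09), PCNA (0.19 ± 0.04), RRM2 (0.32 ± 0.09) and MCM2 (0.15 ± 0.05), and the list had camera adjusted p = 0.00173 and adjusted p = 0.341 with an estimated correlation.

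Among the 10 largest rises at 72 hours were those of the potassium channel KCNJ2 (0.73 ± 0.12), GPR18 (0.70 ± 0.11), CDKN1C (0.63 ± 0.10), the complement genes C1QA (0.63 ± 0.11) and C1QB (0.47 ± 0.10), and MS4A4A (0.61 ± 0.13). Of 20 monocyte markers 4 rose (4 adjusted over the list alone, median 0.04, camera adjusted p = 0.156), among them the growth factor receptor CSF1R (0.36 ± 0.06). The others were CLEC4A (0.16 ± 0.05), SERPINA1 (0.17 ± 0.05) and TLR2 (0.17 ± 0.06), whose calls ended without the volunteer block, and for CLEC4A and SERPINA1 also with the median over probe sets. In all 922 genes differed, 662 higher and 260 lower, and with quantile normalization on top 533 were higher and 400 lower. Without the volunteer block 269 genes passed, with cell type covariates 605 and with array weights 1683. The calls of HLA-DOB, BANK1, CD79A, POU2AF1, RRM2 and MCM2 also ended without the volunteer block, that of RRM2 with cell type covariates and those of SERPINA1 and MCM2 without volunteers of unknown outcome. Plasma cell, erythroid and oxidative phosphorylation lists had medians of -0.09, -0.21 and 0.03, with 2 of 9 falling, 0 of 12 and 6 of 34 rising (2, 0 and 8 adjusted over the list alone). They had camera adjusted p = 0.0149, 0.0382 and 0.0227, and adjusted p = 0.511, 0.808 and 0.808 with an estimated correlation.

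Of 18 immediate early genes tested 13 rose from study entry to 2 weeks after the third vaccination (15 adjusted over the list alone), with a median of 0.55 log2. EGR1 rose by 1.42 ± 0.19, FOS by 1.20 ± 0.14 (36 volunteers, higher in 35 of 36), DUSP1 by 0.72 ± 0.10 and JUNB by 0.67 ± 0.09. The list call held with an estimated correlation (camera adjusted p = 1.6e-56, and adjusted p = 5.27e-08 with an estimated correlation). Of 16 TNF and NF-kB targets 3 rose (4 adjusted over the list alone, median 0.03), namely CXCL8 (1.65 ± 0.22) and the feedback inhibitors TNFAIP3 (0.40 ± 0.09) and NFKBIA (0.38 ± 0.09), while PTGS2 (0.64 ± 0.18) did not pass over all genes (adjusted p = 0.0719). That list had camera adjusted p = 0.000151 and adjusted p = 0.214 with an estimated correlation. Falls were small, with RSRP1 at -0.36 ± 0.05 and the fractalkine receptor CX3CR1 at -0.25 ± 0.06. Only 44 of 7350 genes differed by limma, 28 higher and 16 lower. Without the volunteer block 10 passed, all among the 44, and with array weights 68 passed. The calls of CX3CR1, TNFAIP3 and NFKBIA ended without the block.

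Between study entry and the day of the third vaccination the same family of immediate early genes rose, 15 of 18 with 0 falling (15 adjusted over the list alone, median 0.54). NR4A2 rose by 1.31 ± 0.15, FOS by 1.19 ± 0.14, DUSP1 by 0.96 ± 0.10 and CD69 by 0.77 ± 0.10 in 35 volunteers sampled at both times. The list had camera adjusted p = 3.64e-08 and adjusted p = 0.396 with an estimated correlation. With no filter on dim genes, which adds dim members, the immediate early median was 0.27 here, 0.33 for 2 weeks against study entry and -0.26 at 72 hours. Type I interferon response genes were lower on the day of the third vaccination, 16 of 26 with 0 higher (16 adjusted over the list alone, median -0.32). IFI6 fell by 0.74 ± 0.15, IFIT2 by 0.67 ± 0.14, IFIT5 by 0.66 ± 0.09 and the double-stranded RNA sensor EIF2AK2 by 0.34 ± 0.07. The list did not pass camera (adjusted p = 0.0566), while the sign-flip permutation test of its mean gave adjusted p = 0.0035. That test, added after seeing the data, does not compare the list with other genes. With 4057 genes differing here it shows nothing particular to interferon genes. Of 30 ribosomal protein genes 12 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.04), with camera adjusted p = 0.0128 and adjusted p = 0.909 with an estimated correlation. The ribosomal call also ended with quantile normalization on top (adjusted p = 0.239) and with cell type covariates (adjusted p = 0.436). The transcription factors SOX15 and TCF15 rose by 1.07 ± 0.06 and 0.97 ± 0.05, each higher in 35 of 35 volunteers. The largest falls were those of the protease CTSZ (-0.89 ± 0.11), LILRA5 (-0.86 ± 0.14), the signalling adaptor BCL10 (-0.82 ± 0.07), KCNJ2 (-0.78 ± 0.13) and RNF19B (-0.77 ± 0.09). In all 4057 genes differed, 1491 higher and 2566 lower, and with quantile normalization on top 2068 were higher and 1983 lower. Of 45 bacterial and phage control probe sets, which no human transcript feeds, 6 differed too, by -0.20 to 0.32 log2. With the first 2 principal components of genes below the filter as covariates 2519 genes passed, now more of them higher (1563) than lower (956), with 1385 among the 4057, and SOX15, TCF15, EGR1, CLC and DLST did not.

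At 2 weeks, set against the day of the third vaccination, SOX15 fell by 1.13 ± 0.06 and TCF15 by 0.97 ± 0.05, each lower in 36 of 36 volunteers. DLST, a subunit of the 2-oxoglutarate dehydrogenase complex, fell by 0.92 ± 0.09, the matrix proteoglycan AGRN by 0.82 ± 0.05, the lung surfactant gene SFTPC by 0.81 ± 0.05 and the sodium channel SCNN1A by 0.78 ± 0.04. At 2 weeks AGRN, SFTPC, SCNN1A and TCF15 had means of 5.99, 5.91, 6.04 and 5.48 log2. These lie near or, for TCF15, below the median of all values (5.77) that sets the filter. A shift in array background therefore stays open for them. LILRA5 (0.94 ± 0.14), RNF19B (0.83 ± 0.09), CTSZ (0.82 ± 0.11) and the transcription factor ZEB2 (0.80 ± 0.09) rose. Of 26 type I interferon response genes 12 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.22), with IFI6 at 0.80 ± 0.14, IFIT5 at 0.55 ± 0.09, HERC5 at 0.40 ± 0.11 and EIF2AK2 at 0.28 ± 0.07 (camera adjusted p = 0.455). In all 3779 genes differed, 2341 higher and 1438 lower, and with quantile normalization on top 1822 were higher and 1904 lower. Here too 6 of the 45 control probe sets differed, by -0.31 to 0.24 log2. With the principal components of dim genes as covariates 2233 genes passed, now fewer of them higher (785) than lower (1448), with 1083 among the 3779, and TCF15, DLST, AGRN and SFTPC did not, while the median over probe sets ended the call of AGRN. With no filter on dim genes 5750 of 11939 passed.

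**Figure D3:**
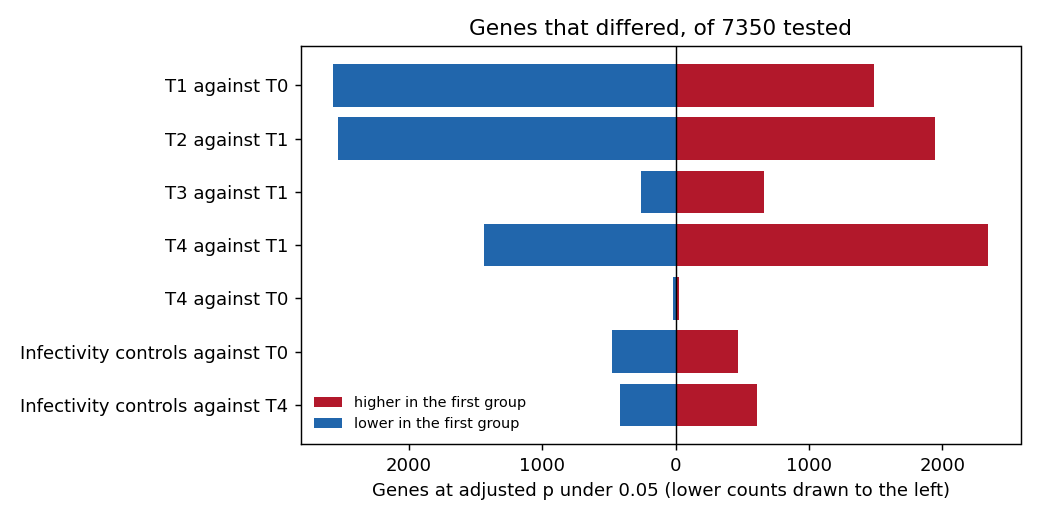
Number of genes at adjusted p under 0.05 in limma (x axis), of 7350 tested, higher (right) or lower (left) in the first group of each comparison with called genes (y axis; T0 study entry, T1 day of the third vaccination, T2 24 hours, T3 72 hours and T4 2 weeks after it). The 24 hour comparison has the most (4470) and 2 weeks against study entry the fewest (44).

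At the sampling 2 weeks after the third vaccination the type I interferon response list was higher in Protected than in NonProtected volunteers in all 26 genes, with a median difference of 0.41 log2, and 0 genes passed, also adjusted over the list alone. ISG15, a ubiquitin-like antiviral protein, differed by 0.66 ± 0.29, MX1 by 0.64 ± 0.30, IFI6 by 0.70 ± 0.31 and EIF2AK2 by 0.41 ± 0.17. The interferon gamma list had a median of 0.20, with CXCL10 at 0.95 ± 0.42, SERPING1 at 0.75 ± 0.35, VAMP5 at 0.36 ± 0.17 and TNFSF10 at 0.35 ± 0.17. The immunoproteasome list had a median of 0.10, with PSMB9 at 0.23 ± 0.12, PSMB10 at 0.13 ± 0.09, PSME1 at 0.11 ± 0.07 and POMP at 0.09 ± 0.06, and 0 genes of either list passed, also adjusted over the list alone. Camera called all these lists (adjusted p = 1.72e-15, 3.78e-06 and 0.00179), and each had adjusted p = 0.401 with an estimated correlation. The mean of the type I list was 8.29 ± 0.93 log2 (SD, n = 11) in Protected and 7.86 ± 0.31 (SD, n = 15) in NonProtected volunteers, a difference of 0.43 (permutation test, 2-sided, adjusted p = 0.536 over the 20 lists). Only 2 of the 11 Protected arrays lay above all NonProtected arrays, and leaving out 1 Protected array brought the difference to 0.21. With array weights the list median was 0.20, and the interferon gamma and immunoproteasome lists lost their calls. At study entry the median was -0.29 with 0 of 26 genes higher in Protected volunteers, but 0.21 with cell type covariates and 0.03 with the principal components of dim genes as covariates. With cell type covariates camera called the list in the other direction (adjusted p = 5.67e-07). In the main fit at study entry 0 genes passed, also adjusted over the list alone (camera adjusted p = 6.56e-06, adjusted p = 0.606 with an estimated correlation, and adjusted p = 0.189 without the arrays that stood apart).

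**Figure D4:**
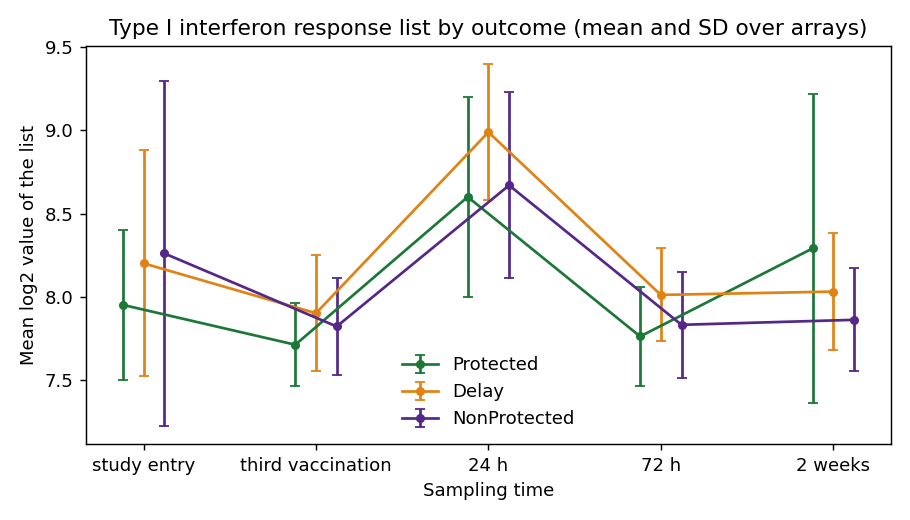
Mean log2 value over the 26 tested type I interferon response genes (y axis) by sampling time (x axis) and challenge outcome (colours); points are means over 9 to 15 arrays and bars are SDs. All groups peak at 24 hours, and at 2 weeks the Protected group has the highest mean (8.29) and the widest SD (0.93).

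No single gene separated Protected from NonProtected volunteers at adjusted p under 0.05. In limma 0 of 7350 genes passed at study entry, on the day of the third vaccination, at 24 hours, at 72 hours and at 2 weeks, with 131, 328, 157, 206 and 169 genes at an unadjusted p under 0.05. All other settings run also gave 0 at each of these times. The smallest p at 2 weeks was that of MKLN1, 0.27 ± 0.07 log2 higher in Protected volunteers (adjusted p = 0.999). ERAP2, which trims peptides for MHC class I and whose expression depends on a common haplotype, was 1.34 ± 0.40 higher (adjusted p = 0.999). On the day of the third vaccination TRMT1L was 0.45 ± 0.11 higher (adjusted p = 0.931), and at study entry CLIC5 was 0.30 ± 0.07 lower (log2 difference -0.30, adjusted p = 0.999). CNNM3 at 24 hours (-0.42 ± 0.12) and UPF2, of nonsense-mediated decay, at 72 hours (0.24 ± 0.06) had the smallest p of their times.

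Between volunteers labelled Delay and NonProtected ones 0 of 7350 genes passed in limma at 2 weeks and 895 had an unadjusted p under 0.05. The helicase DHX29 was 0.25 ± 0.05 log2 higher, the cell cycle regulator CKS2 0.64 ± 0.14 higher and MKLN1 0.33 ± 0.07 higher in the Delay group, and the immune cell receptor CD84 differed by -0.38 ± 0.08 (n = 11 and 15). Their adjusted p was 0.0791 for DHX29, CD84 and CKS2 and 0.085 for MKLN1. Array weights gave 144 genes and the principal components of dim genes 111, and all these genes and NAB1 (0.40 ± 0.09) passed in both. The 3' minus 5' signal of ACTB was 0.874 ± 0.456 log2 (SD, n = 11) in Delay, 0.544 ± 0.254 (n = 15) in NonProtected and 0.559 ± 0.219 (n = 11) in Protected volunteers, and that of GAPDH 0.834 ± 0.545, 0.510 ± 0.202 and 0.604 ± 0.146. For Delay against NonProtected permutation tests gave p = 0.0173 for ACTB and 0.0171 for GAPDH, each with adjusted p = 0.208 over 24 such tests. Between Protected and Delay volunteers 0 genes passed and 643 had an unadjusted p under 0.05. TM2D3 (-0.35 ± 0.08), HMGN3 (-0.24 ± 0.06) and MORF4L2 (-0.24 ± 0.05) led, each with adjusted p = 0.238, and array weights gave 10 genes and the principal components 5. All other settings run gave 0 in both comparisons.

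At 5 days after challenge the cell cycle list was higher in Protected than in NonProtected volunteers, 20 of 21 genes with a positive difference and a median of 0.19 log2. MKI67, a marker of proliferating cells, differed by 0.42 ± 0.17, ZWINT by 0.42 ± 0.19, CDK1 by 0.26 ± 0.12 and TYMS by 0.55 ± 0.27. Immediate early genes had a median of -0.16, with RGS1 at -0.37 ± 0.17, G0S2 at -0.50 ± 0.27, DUSP1 at -0.39 ± 0.23 and MAFF at -0.12 ± 0.07, and 0 genes of either list passed, also adjusted over the list alone. Camera called both (adjusted p = 1.2e-07 and 0.000146), with adjusted p = 0.429 for each with an estimated correlation and adjusted p = 0.735 by permutation of list means, and the immediate early call ended with cell type covariates. Against the Delay group, NK and cytotoxic markers of Protected volunteers had a median of -0.23, with granzyme B (GZMB) at -0.65 ± 0.23, perforin (PRF1) at -0.42 ± 0.21, NCAM1, which encodes CD56, at -0.50 ± 0.25 and KLRF1 at -0.54 ± 0.28, and 0 of 20 passed, also adjusted over the list alone (camera adjusted p = 7.74e-07, and adjusted p = 0.771 with an estimated correlation). With the median over probe sets NCAM1 turned to 0.087. In limma 0 of 13381 genes passed for Protected against NonProtected, Delay against NonProtected and Protected against Delay, in every setting run, with 492, 498 and 375 genes at an unadjusted p under 0.05. MAPK10 (0.27 ± 0.07), GIMAP2 (-0.29 ± 0.07) and NPTX1 (0.19 ± 0.05) were among those with the smallest p in these comparisons. GSTM1 (-0.63 ± 0.18) and GSTM2 (-0.71 ± 0.21) followed in the last of them, and their signals cross-hybridise and depend on a common gene deletion.

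The change after the third vaccination was not shown to differ between Protected and NonProtected volunteers for any gene. Interaction tests in limma gave 0 of 7350 genes for the change to 24 hours, 72 hours and 2 weeks, and 0 in every other setting run, with 173, 96 and 435 genes at an unadjusted p under 0.05. From the day of the third vaccination to 2 weeks all 26 type I interferon genes rose more or fell less in Protected volunteers, with a median difference of 0.52 log2. OAS3 differed by 0.80 ± 0.28, EIF2AK2 by 0.49 ± 0.17, ISG15 by 0.83 ± 0.34 and IFI44L by 1.09 ± 0.45, and 0 passed, also adjusted over the list alone. Camera called the list (adjusted p = 1.34e-14, and adjusted p = 0.367 with an estimated correlation), and the permutation test of the list mean gave adjusted p = 0.166. With array weights its median was 0.25. This change uses the Protected arrays of 2 weeks, where leaving out 1 array brought the type I difference from NonProtected from 0.43 to 0.21.

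Of 25 constitutive proteasome genes 8 were higher in the infectivity controls than in vaccinated volunteers at 2 weeks (9 adjusted over the list alone, median 0.12), among them PSMC6 (0.26 ± 0.06), PSMD12 (0.20 ± 0.06), PSMC1 (0.14 ± 0.04) and PSMD4 (0.12 ± 0.04). Of 8 cell cycle genes 3 were higher (7 adjusted over the list alone, median 0.35), namely PCNA (0.33 ± 0.08), MCM6 (0.29 ± 0.09) and PTTG1 (0.28 ± 0.10), while MCM2 had 0.38 ± 0.14 (adjusted p = 0.0513). Of 20 monocyte markers 2 were lower (2 adjusted over the list alone, median -0.21), CSF1R (-0.53 ± 0.15) and SERPINA1 (-0.49 ± 0.14), while FCN1 (-0.40 ± 0.15) and CTSB (-0.31 ± 0.12) did not pass. These lists had camera adjusted p = 0.000193, 0.000906 and 0.000906, and each had adjusted p = 0.685 with an estimated correlation. In all 611 genes were higher and 414 lower (n = 12 and 37), led by MYOM2 (1.24 ± 0.40) and ETS1 (0.83 ± 0.21) upward and CTSZ (-1.11 ± 0.22) and the chromatin factor BPTF (-0.86 ± 0.14) downward. Against study entry 471 were higher and 478 lower (n = 12 and 36), led by CXCL8 (1.45 ± 0.25), CD69 (0.87 ± 0.20), CTSZ (-1.18 ± 0.22) and BPTF (-0.90 ± 0.14). CTSZ had a mean of 6.60 log2 in the infectivity controls, 6.92 on the day of the third vaccination, 7.79 at study entry and 7.71 at 2 weeks. In that order ETS1 had 6.90, 6.86, 6.09 and 6.07, and DLST 7.73, 7.89, 6.97 and 6.96. These genes lay nearer the day of the third vaccination, whose shift may be a batch, but JUNB did not (8.93, 9.68, 9.03 and 9.69). How many genes share that shift was not tested. The bioC hybridisation controls, bacterial transcripts added to every sample, were lower on the infectivity control arrays by up to 1.55 log2 (lowest change -1.55 against 2 weeks, -1.48 against study entry), and 4 and 5 control probe sets differed. Without the arrays that stood apart 598 genes differed against 2 weeks, and with the principal components of dim genes 289 (128 higher and 161 lower), and 408 against study entry. With cell type covariates 407 were higher and 447 lower against 2 weeks. With these components MYOM2 and all named proteasome, cell cycle and monocyte genes that had passed lost their calls, as did the cell cycle (adjusted p = 0.055) and monocyte (adjusted p = 0.514) lists. Without the arrays that stood apart MYOM2, PSMC1, PSMD12, SERPINA1, MCM6 and PTTG1 did so too.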

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

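The sign-flip and permutation tests of list means were chosen after the results were seen; the other tests here were planned. In 100 tests, each of the mean value of a gene list in a group of 7 to 10 arrays, 11 found an array far from the others, by the gap to the nearest array divided by the whole range. Chance alone marks about 1 in 20 groups, but the 100 tests were not independent, since the lists were tested on the same arrays. The groups of unknown outcome were the same 7 volunteers at each time, so 1 person can be marked repeatedly. Among the 9 Delay arrays at 24 hours, the highest stood apart for immediate early genes (0.50 of the range), and the lowest for monocyte markers (0.59) and for oxidative phosphorylation genes (0.73). Among the 10 Delay arrays at 72 hours, it was the highest for cell cycle genes (0.53) and the lowest for ribosomal protein genes (0.61). Among the 7 arrays of unknown outcome, the highest stood apart for plasma cell markers on the day of the third vaccination (0.57) and at 24 hours (0.72), and for erythroid markers on that day (0.82), at 24 hours (0.72) and at 72 hours (0.89). So did the highest for granulocyte markers at 72 hours (0.63).

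In the tests of whether the change from the day of the third vaccination differed between Protected and NonProtected volunteers, camera with a preset correlation called 17 lists. None was called with an estimated correlation or by permutation of list means. For the change to 24 hours the median differences of log2 changes were 0.04 for the constitutive proteasome, 0.11 for immediate early genes, 0.30 for erythroid markers and 0.03 for oxidative phosphorylation. For the change to 72 hours they were -0.15 for B cell and -0.21 for granulocyte markers. For the change to 2 weeks, interferon and presentation lists had 0.52 (type I interferon response), 0.37 (interferon gamma response), 0.17 (immunoproteasome and PA28) and 0.12 (MHC class I presentation). TNF and NF-kB targets had 0.14, immediate early genes 0.24, monocyte markers 0.10 and plasma cell markers 0.27. T cell markers had -0.11, B cell markers -0.11 and ribosomal protein genes -0.09. Probe sets named for no gene or for several genes entered no comparison above. At 24 hours 961 of 3130 such probe sets differed from the day of the third vaccination, 309 higher and 652 lower, with a highest change of 2.46 log2. Dim probe sets were not filtered out here, so this share is not comparable with that of the genes tested.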

How the results depend on the processing

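Alternatives that left out arrays that stood apart or used principal components of dim genes were chosen after seeing the data, as were the lists described with named members. Of 168 counts of called genes 152 stayed within 1.5 times, and of 2684 values of named genes 2515 kept direction and side of the threshold, 143 lost and 18 gained a call, and 8 reversed. Of 1214 list values 895 held, 308 lost the call and 11 reversed. With an estimated correlation only 4 of 138 list calls held and 134 ended, so most list calls rest on the preset correlation. Over the 4 members with the smallest p of all lists and the named genes called in longitudinal comparisons, 52 of 3260 values reversed, 38 of them with principal components of dim genes. Without the volunteer (replicate) block 269 genes passed at 72 hours and 10 for 2 weeks against study entry. The other longitudinal counts stayed within 1.5 times without it, all interaction counts stayed at 0, and 4 of 48 list calls ended. With cell type covariates and the block 1035 passed at 24 hours and 605 at 72 hours. There IRF8 had -0.034, CD1C 0.006, RPL35 0.025, the type I list 0.022 and the ribosomal list 0.033 at 24 hours, and the type I list -0.002 for 2 weeks against study entry. In the main fit camera with the preset correlation had called the type I list for 2 weeks against study entry. With the covariates its camera direction turned and it did not pass (adjusted p = 0.654). With such covariates Protected against NonProtected at study entry had 0.211 (type I), 0.065 (interferon gamma), 0.006 (immunoproteasome) and -0.05 (ribosomal). The ribosomal value there was -0.014 without arrays that stood apart and -0.017 with principal components, which gave 0.03 for type I. Array weights gave 1683 genes at 72 hours, 68 for 2 weeks against study entry, 144 for Delay against NonProtected and 10 for Protected against Delay at 2 weeks, and 0.01 for the constitutive proteasome in Protected against NonProtected at 2 weeks, where camera turned downward. Their weights stopped short of convergence in some fits. Principal components gave 2519 (day of the third vaccination against study entry), 2233 (2 weeks against that day), 111 (Delay against NonProtected) and 5 (Protected against Delay) at 2 weeks, 408 and 289 (infectivity controls against study entry and 2 weeks). The latter was 598 without arrays that stood apart. With no filter 5750 passed for 2 weeks against the day of the third vaccination, with more genes tested. The median over probe sets gave ATF5 -0.014 (Protected against NonProtected) and PDS5B 0.258 (Protected against Delay) at 2 weeks, and ZNF880 0.002, EIF3M 0.08 (Delay against NonProtected) and NCAM1 0.087 (Protected against Delay) 5 days after challenge. Apart from the filter, the cause was not tested. List tests were not run with the random block, and covariates give no value for the 6 lists they are made from.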

Other observations

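The comparison of calls among genes below the filter, the type I interferon test with cell type covariates, the comparison of cell type lists at 24 hours, the monocyte tests at 72 hours and study entry, and the batch test of immediate early genes at study entry were chosen after the results were seen.

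Between study entry and the day of the third vaccination 4057 genes differed, and between that day and 2 weeks later 3779, while study entry and 2 weeks differed in 44 genes. RNA degradation was argued against for study entry against the day of the third vaccination, since the 3' minus 5' signal of ACTB moved by 0.077 log2 (95% interval -0.023 to 0.185) and that of GAPDH by -0.045 (-0.135 to 0.039). A change in cell composition alone was argued against by the 4146 genes that passed with cell type covariates, 3693 of them among the 4057. Array processing batch stays open, since 6 of 45 control probe sets differed, and so does array background or hybridisation, since 44.5% of genes below the filter were called against 54.5% above it (13.8% and 58.7% at 24 hours). A lasting effect of the earlier vaccinations as the only cause was argued against. At 2 weeks, after a further vaccination, 44 genes differed from study entry, against 4057 on the day of the third vaccination. SOX15 had means of 7.65, 7.57 and 7.47 log2 on that day, at 24 hours and at 72 hours. It had 6.56 at study entry and 6.52 at 2 weeks. A passing effect of the earlier vaccinations cannot be told apart from an array batch here, and the higher SOX15 and TCF15 on that day may be either.

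At 24 hours interferon and monocyte lists were higher and lymphocyte lists lower. More monocytes alone was argued against for the interferon gamma list: 14 of its 16 risen genes stayed called with cell type covariates (median 1.25 to 0.59 log2, median SE 0.08 to 0.10). List means only approximate cell shares, so they can leave part of an effect of cell types in the values. Of 25 type I genes 2 stayed (0.92 to 0.03, SE 0.11 to 0.13), so for these a shift in cell types stays open, though covariates made from the same arrays can also absorb a shared response. A lower T cell share that raises every other cell type alike was argued against, since all 3 of the B cell, platelet and erythroid lists had negative medians with intervals below 0. The platelet and erythroid lists did not pass camera, and these intervals do not cover the correlation between genes. A larger monocyte share would also lower the values of these lists, so this test does not bear on it. Array batch was argued against by 0 of 45 differing control probe sets, a weak detector given the 6 above, and a response of the cells to the third vaccination stays open and untested.

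Immediate early genes were lower at study entry and at 72 hours than on the day of the third vaccination and 2 weeks after it. A change in monocyte share was argued against, since monocyte markers had a median of 0.04 log2 at 72 hours against -0.58 for the immediate early list, and against study entry -0.10 on the day of the third vaccination and -0.05 at 2 weeks, where the immediate early list had 0.54 and 0.55. Array batch was argued against, by the same weak detector, for 72 hours (1 of 45 control probe sets differed) and for 2 weeks against study entry (0 of 45). For study entry against the day of the third vaccination array batch stays open, since 6 of 45 differed. These genes respond to handling, so a different time from blood draw to processing, not used here, could give the pattern and stays open beside a biological change.

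Other splits of the same arrays, 100 per comparison with the real one included, tested whether chance can give as many genes. In longitudinal comparisons the times were swapped within volunteers sampled at both. Arrays of the other volunteers kept their time, so these splits can keep part of the real difference. Chance was argued against for the day of the third vaccination against study entry (4057 genes, highest other split 1658, 1 of 100 as large), 24 hours (4470, 768, 1), 72 hours (922, 1, 1) and 2 weeks against the day of the third vaccination (3779, 686, 1). With 100 splits no share under 1 of 100 can be shown. Why other splits called as many as 1658, 768 and 686 genes was not tested. For 2 weeks against study entry 2 of 100 splits were as large, and the highest other called 136 genes against 44, which points to a structure of the samples, or to genes that move together, that was not tested. For the infectivity controls the real counts were 949 and 1025 against 17 and 23, with 1 of 100 as large in each. Such splits cannot tell a difference between groups from an array batch. In the outcome and interaction comparisons the real count was 0, which every split reaches (100 of 100), so these splits say nothing on chance. The highest other splits of Protected against NonProtected called 2, 4, 82, 1 and 3 genes from study entry to 2 weeks and 3 after challenge. Delay against NonProtected had 6 and 2 and Protected against Delay 1 and 1, at 2 weeks and after challenge. The interactions had 1, 1 and 174. The 82 at 24 hours and the 174 for the change to 2 weeks point to a structure of the samples, or to genes that move together, that was not tested.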
